A study of Mus musculus with 8 samples.

How the data were processed

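Total RNA from Peyer's patches of 8 C3H/HeJ mice was read on a single-colour Affymetrix mouse array with a biotin label. The deposited values are probe set intensities on a linear scale, normalized by the authors, between 1.86 and 14749. Per the submitters' processing notes MAS5 was used; its version, scaling target and background step are not given in the sources used here. Of the 45101 probe sets, 23229 (51.5%) held exactly equal values on 2 or more arrays, and the 2 to 98% trimmed means of the arrays ran from 65.1 to 68.2 and were not equal, so the step that summarised probes into these intensities was not settled and the values were used as deposited. No scan date, array batch or raw image file was available. The number of arrays limits the precision of every value.

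Samples were grouped by the treatment and sex in the labels as female control (n = 1), male control (n = 1), female OVA (n = 2) and male OVA (n = 4). Intensities were taken to log2(value + 4.88), where 4.88 is the 25th percentile of all values, with no further scaling between arrays. The 64 AFFX control probe sets were left out, and probe sets above the median of the mean log2 value (an intensity of 11.9) were tested, 22518 in all. The probe set annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, naming 18194 genes. The gene identifiers of 34754 of the 34958 were in the reference gene table, and 0 symbols were updated. A gene was represented by its brightest probe set past the filter that names it alone, which left 11988 genes.

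Comparisons used lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 8 arrays, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. OVA against control and female against male came from 1 additive fit of treatment and sex with 5 residual degrees of freedom. The difference in the OVA effect between males and females came from a fit of 4 group means with 4 residual degrees of freedom, in which each lone control is assumed to vary like the other arrays. The median residual SD was 0.166 log2 and the prior degrees of freedom were 3.59. Gene lists were tested for OVA against control with camera at a preset correlation of 0.01, with at least 5 measured genes per list, and again with an estimated correlation and with fry. Before the data were examined 39 lists were fixed, of cell types of the patch and the gut wall, immune responses, stress, metabolism, contaminating tissues and sex chromosome markers. List scores are mean log2 intensities over the measured genes. They were compared by exact permutation over the 28 splits into 2 and 6 arrays, and related to each other by exact permutation over 40320 pairings. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for tables, correlations and figures.

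The genes named were set by a rule fixed before the data were examined. For OVA against control these were the 12 genes on each side with the largest change past the threshold, filled by smallest p where fewer passed, in which all OVA arrays lie on the same side of both controls. To these were added the 3 genes of smallest p in each list and 20 genes of allergy and mucosal immunity, 9 of which passed the filter. For the sexes, Xist and 4 Y-linked genes and the 8 genes on each side were named, without the separation rule. For the difference between sexes in the OVA effect, the 5 genes of smallest p on each side were named. Of the 164 genes so named, 58 had another probe set past the filter and 11 had one of opposite sign.

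The methods were tested on simulated data with 200 changed probe sets and the spread of each probe set after the shrinkage of eBayes. For OVA against control, 3% of 1.5-fold, 88% of 2-fold and 100% of 4-fold changes were recovered. For the sexes the shares were 32%, 92.5% and 99.5%, and for the difference between the sexes in the OVA effect 0%, 0% and 85%. Noise was drawn independently for each probe set, so variation shared between probe sets was absent. These shares may therefore not hold for these arrays. A simulated shift of 0.2 log2 in the germinal centre list of 18 genes gave an adjusted p of 0.0214 with the preset correlation and 0.934 with an estimated one. A shift of 0.4 gave 5.39e-12 and 0.0178. Genes were simulated as independent, while the estimated correlation of this list in the data was 0.393. The simulation therefore cannot show how often the preset correlation calls lists wrongly in these arrays.

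Alternatives fixed before the data were examined were a pseudocount of 1 or of the median of all values, quantile normalization, median centring, no filter, a filter at the 75th percentile, trend and robust variance, array weights, no covariate, contrasts within each sex, the OVA arrays alone for the sexes, the mean of all probe sets of a gene, and leaving out each array in turn. Added after the data were seen were the B cell score minus the barrier score as a covariate, leaving out male OVA 5 and 8 together, leaving out male control 8 and male OVA 8 together, and 6 further gene lists, namely high endothelial venules, mammary gland, ileum, proximal small intestine, cholesterol synthesis and lung. Probe sets that name several genes or none entered the tests but not the gene lists. All deposited arrays were used. With 1 control left out, the additive fit gave the OVA effect within the other sex and the sex difference within the OVA arrays. Those settings therefore repeat contrasts named above.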

Results

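Gene expression was measured in Peyer's patches, the lymphoid follicles of the intestinal wall, of 8 C3H/HeJ mice. C3H/HeJ is an inbred strain with a defective Tlr4, the receptor for bacterial lipopolysaccharide. Ovalbumin (OVA), an egg white protein used as a model food allergen, was given by gavage to 6 mice at 40 mg/kg each day for 28 days, starting at 6 weeks of age. The other 2 mice were controls given saline. The groups were 1 female control (replicate 7), 1 male control (replicate 8), 2 female OVA mice (replicates 2 and 12) and 4 male OVA mice (replicates 1, 5, 8 and 13). Each sample was read on a single-colour array of 45101 probe sets, whose deposited intensities ran from 1.86 to 14749. The 2 to 98% trimmed mean of an array lay between 65.1 and 68.2. The number of arrays limits the precision of every value. The tested set held the 22518 probe sets above the median intensity, which named 11988 genes. The labels give Peyer's patches as the tissue, while their extraction text speaks of brain tissue from a patient. Of 19 neuron and glia genes fixed beforehand, 6 passed the intensity filter, against 19 of 20 B cell genes, and the 17 with a probe set had a median intensity of 6.39, below the filter at 11.9.

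The comparison of OVA with saline addressed which transcripts of the gut lymphoid tissue differed after repeated oral exposure to a food allergen. Gene groups of B cells, germinal centres, T cells, antigen presentation and the follicle-associated epithelium were higher in OVA mice. Groups of the epithelial barrier, goblet cells, enterocytes, crypts and the interferon response were lower, although the enterocyte score was not lower in most male OVA mice. None of these groups passed camera with an estimated correlation (smallest adjusted p = 0.863). The median B cell gene was 0.56 higher on the log2 scale, and the median barrier gene was at -0.23. The B cell score, the mean log2 intensity over the group, was 7.67 ± 0.08 (SD, n = 2) in controls and 8.14 ± 0.40 (SD, n = 6) in OVA mice. Of the 36 gene lists tested with camera at a preset correlation of 0.01, 16 passed, 9 higher and 7 lower. As many lists were called in 10 of the 28 splits of the arrays into 2 and 6, the real one included. The other splits called a median of 13. Estimated correlations of the 16 lists were 0.098 to 0.854, above the preset value. None of the 36 lists passed with an estimated correlation (smallest adjusted p = 0.863) or with fry (smallest adjusted p = 0.649). No single probe set passed with limma (smallest adjusted p = 0.21), although 2524 had an unadjusted p under 0.05, 1550 of them higher and 974 lower, where 1126 were expected by chance. Of the 28 splits, 3 gave as many such probe sets as the real one, itself included, and the highest other gave 6386.

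**Figure D1:**
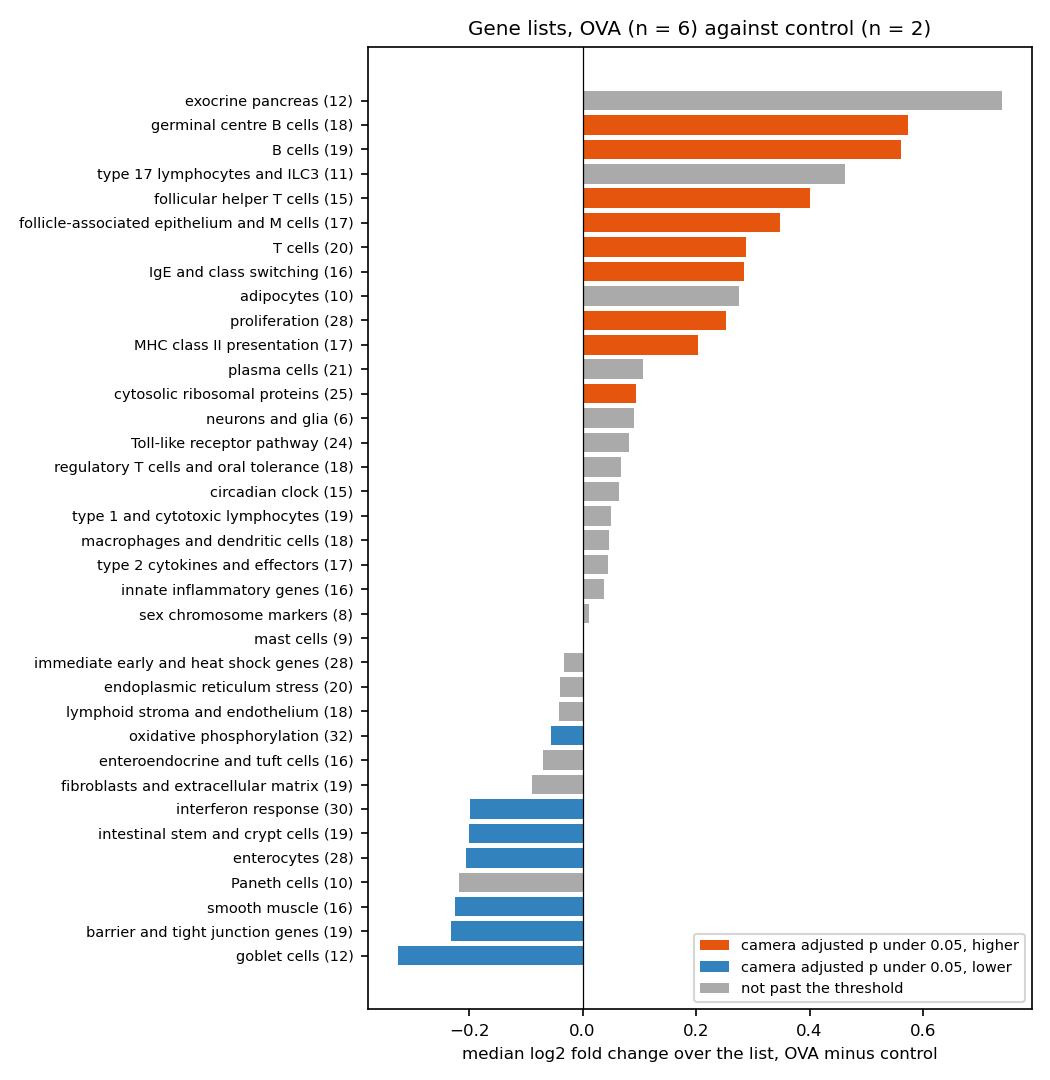
Median log2 fold change, OVA (n = 6) minus control (n = 2), of each of the 36 tested gene lists, with the number of measured genes in brackets and colour for the 16 lists past the threshold of camera with a preset correlation of 0.01. No list passed with an estimated correlation.

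Genes of the B cell follicle stood together on the higher side. All 19 measured B cell genes were higher (median 0.56, adjusted p = 4.25e-05), as were 16 of 18 germinal centre genes (median 0.57, adjusted p = 0.000529) and 12 of 16 genes of IgE and class switching (adjusted p = 0.0188). With an estimated correlation the adjusted p was 0.863 for each of these 3 lists. Among B cell genes, Vpreb3, part of the surrogate light chain family, was 0.89 ± 0.27 (SE) higher, Fcrla 0.92 ± 0.29 (SE) and Ebf1, a transcription factor of B cell identity, 0.58 ± 0.22 (SE). In the germinal centre list, Rgs13, a regulator of G protein signalling in germinal centre B cells, went from 97.8 ± 25.7 (SD, n = 2) in controls to 229.7 ± 110 (SD, n = 6). Basp1 was 0.67 higher and the DNA glycosylase Neil1 0.90 higher. In the class switching list, Batf was 0.65 ± 0.16 (SE) higher, Tnfrsf13c, the receptor for the B cell survival factor BAFF, 0.81 ± 0.31 (SE) and Ighm, the IgM heavy chain, 0.56 ± 0.22 (SE). T cell genes were higher in 17 of 20 (median 0.29, adjusted p = 0.00165) and follicular helper T cell genes in 14 of 15 (median 0.40, adjusted p = 0.00392). For both T cell lists the adjusted p with an estimated correlation was 0.863. Cd8b1, a chain of the CD8 coreceptor, went from 18.9 ± 1.75 (SD, n = 2) to 31.3 ± 3.33 (SD, n = 6) and passed when adjusted over the list alone, the 1 member to do so. Lef1 was 0.50 ± 0.19 (SE) higher, Cd247 0.45 ± 0.18 (SE), Sh2d1a, an adaptor needed for T cell help to B cells, 0.74 ± 0.25 (SE) and Icos 0.55 ± 0.20 (SE). All 17 genes of MHC class II presentation were higher (median 0.20, adjusted p = 0.00167; adjusted p = 0.863 with an estimated correlation), among them the costimulator Cd86 by 0.79 ± 0.24 (SE). Of the 28 proliferation genes, all were higher (median 0.25, adjusted p = 0.000387; adjusted p = 0.889 with an estimated correlation), with Pcna going from 1849 ± 258 (SD, n = 2) to 2365 ± 319 (SD, n = 6). All 25 ribosomal protein genes were higher by a small amount (median 0.09, adjusted p = 0.0204; adjusted p = 0.899 with an estimated correlation), Rpl37 by 0.39 ± 0.12 (SE). No member of the B cell, germinal centre, class switching, follicular helper, MHC class II, proliferation or ribosomal list passed when adjusted over the list alone. Leaving out 1 control made the OVA effect the contrast within the other sex, against its lone control. Without male control 8 the germinal centre (adjusted p = 0.0887), T cell (0.272), MHC class II (0.0812), class switching (0.0876) and ribosomal (0.272) lists did not pass, and without female control 7 neither did the follicular helper (0.0829), proliferation (0.0672) and class switching (0.14) lists. Without female OVA 12 the class switching (0.0699) and ribosomal (0.209) lists did not pass, nor without male OVA 8 (0.094) or with array weights (0.191) the ribosomal list.

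Genes of the follicle-associated epithelium and M cells, the cells that carry antigen from the gut lumen into the patch, were higher in 14 of 17 (median 0.35, adjusted p = 0.000324). With an estimated correlation the adjusted p of this list was 0.863. Ccl20, a chemokine of this epithelium, went from 151.1 ± 16.3 (SD, n = 2) to 285.8 ± 66.9 (SD, n = 6), a log2 difference of 0.84 ± 0.23 (SE). Ccl9 was 0.49 ± 0.15 (SE) higher and Anxa5 0.48 ± 0.17 (SE). The score of this list, relative to the mean of the 8 arrays, was highest in female OVA 12 (0.37) and male OVA 8 (0.29). These mice also had the highest B cell scores, so a change in this epithelium was not told apart from the amount of follicle. The other epithelial groups lay on the lower side. All 19 barrier and tight junction genes were lower (median -0.23, adjusted p = 1.32e-05), as were all 12 goblet cell genes (adjusted p = 0.000529) and 18 of 19 stem and crypt genes (median -0.20, adjusted p = 8.89e-05). With an estimated correlation the adjusted p was 0.863 for each of these 3 lists. Cldn2, a pore-forming claudin, had a log2 difference of -0.86 ± 0.28 (SE), Cldn23 of -0.68 ± 0.25 (SE) and Tjp3 of -0.52 ± 0.21 (SE). Clca1, a secreted goblet cell protein, went from 1816 ± 290.0 (SD, n = 2) to 1312 ± 337 (SD, n = 6). Among crypt genes, the cotransporter Slc12a2 was at -0.33 ± 0.12 (SE), the transcription factor Cdx1 at -0.47 ± 0.18 (SE) and the stem cell receptor Lgr5 at -0.45 ± 0.18 (SE). Enterocyte genes were lower in 26 of 28 (median -0.21, adjusted p = 0.000533; adjusted p = 0.889 with an estimated correlation), including the brush border peptidases Mep1b (-0.44) and Anpep (-0.45). The enterocyte score was 10.48 in the female control and 10.03 and 9.59 in female OVA mice. It was 10.26 in the male control and 10.42, 10.56, 10.04 and 10.42 in male OVA 1, 5, 8 and 13. Smooth muscle genes were lower in 15 of 16 (adjusted p = 0.00129; adjusted p = 0.863 with an estimated correlation), with the myosin Myh11 at -0.47 ± 0.17 (SE), although its second probe set had the opposite sign. Genes of oxidative phosphorylation were lower in 28 of 32 by a small amount (median -0.06, adjusted p = 0.0171; adjusted p = 0.899 with an estimated correlation), among them Ndufs1 at -0.26 ± 0.12 (SE). In none of these lists did a member pass when adjusted over the list alone. Leaving out male control 8 gave the contrast within females, and leaving out female control 7 that within males. Without male control 8 the goblet (adjusted p = 0.272), crypt (0.0957) and smooth muscle (0.109) lists did not pass, without female control 7 the enterocyte (0.164) and oxidative phosphorylation (0.75) lists turned to the higher side, and without female OVA 12 these 2 lists stayed lower but did not pass (0.212 and 0.111). Without male OVA 8 (0.094) or with array weights (0.0562) the oxidative phosphorylation list did not pass.

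The scores varied among OVA mice as well. Relative to the mean of the 8 arrays, the B cell score was -0.30 and -0.41 in the controls, 0.58 in female OVA 12, 0.64 in male OVA 8 and between -0.30 and 0.05 in the other 4 OVA mice. Barrier genes ran the other way, at 0.12 and 0.37 in the controls, -0.26 in female OVA 12 and -0.44 in male OVA 8. Across the 8 arrays the B cell and barrier scores had r = -0.95 (exact permutation p = 7.44e-05, adjusted 0.000372) and rho = -0.98 (exact permutation p = 0.000397, adjusted 0.00198). Leaving out the 2 arrays farthest from the median gave r = -0.92, and the 6 OVA arrays alone r = -0.95. B cell and T cell scores had r = 0.97 (exact permutation p = 0.000843, adjusted 0.00211) and rho = 0.83 (exact permutation p = 0.0154, adjusted 0.0384), with r = 0.80 without the 2 extreme arrays and r = 0.97 within OVA arrays. B cell and enterocyte scores had r = -0.72 (exact permutation p = 0.0446, adjusted 0.0744) and rho = -0.52 (exact permutation p = 0.197, adjusted 0.328), and r = -0.01 without the 2 extreme arrays, so this relation rests on those arrays. The B cell score showed r = 0.13 with the beta-actin 3′ to 5′ ratio, a measure of RNA integrity (exact permutation p = 0.802, adjusted 0.993; rho = -0.05, exact permutation p = 0.935, adjusted 0.935), and r = 0.01 with the Gapdh ratio (exact permutation p = 0.993, adjusted 0.993; rho = -0.12, exact permutation p = 0.793, adjusted 0.935). Without the 2 extreme arrays these values were -0.75 and -0.66, and within OVA arrays 0.60 and 0.63. These 5 relations formed the family over which p was adjusted. Both ratios were lower in 5 of the 6 OVA mice than in either control. The beta-actin ratio was 1.43 and 1.54 in controls, 1.58 in male OVA 8 and 1.29 to 1.37 in the other OVA mice (exact permutation p = 0.179), and the Gapdh ratio 0.896 and 1 in controls, 0.96 in male OVA 8 and 0.834 to 0.891 in the others (exact permutation p = 0.107). Permuting treatment over the 8 arrays, an exact test whose smallest possible p is 0.036, gave p = 0.107 for the B cell score, 0.143 for the barrier score and 0.0357 for the crypt score, and no list passed after adjustment (smallest adjusted p = 0.429).

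**Figure D2:**
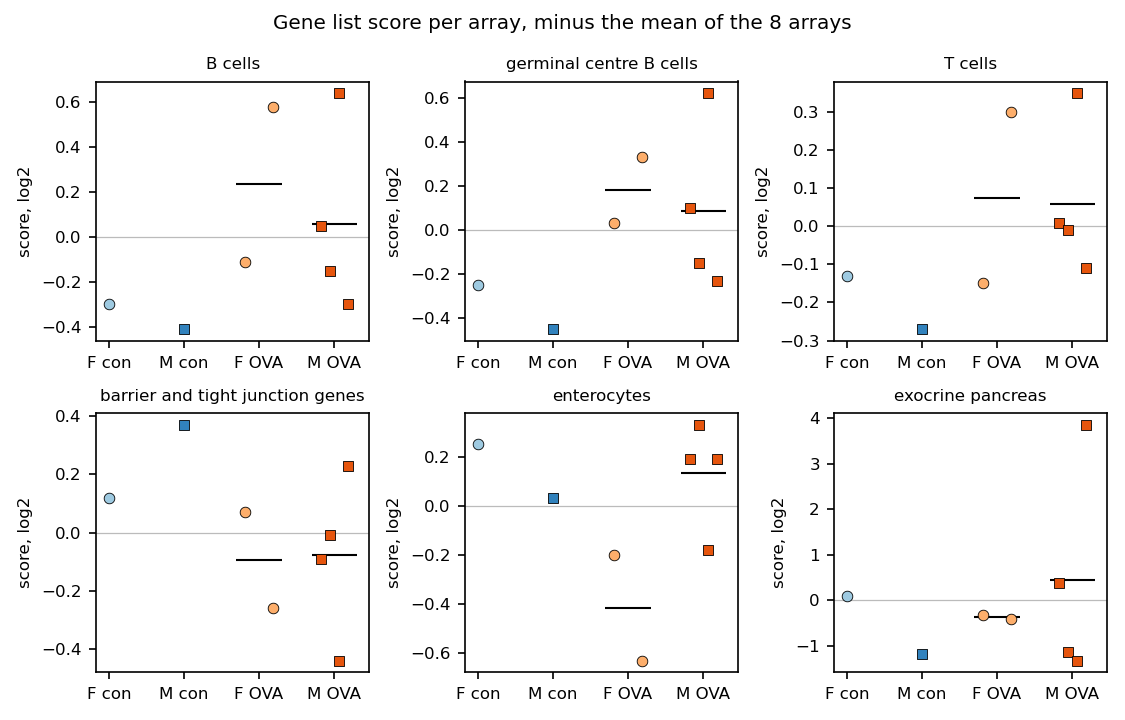
Score per array (mean log2 intensity of the list, minus the mean of the 8 arrays) for 6 gene lists in female and male (F, M) control (con) and OVA mice, each point 1 mouse and each line the mean of a group of more than 1 mouse. Female OVA 12 and male OVA 8 have the highest B cell scores, 0.58 and 0.64, and male OVA 13 stands at 3.85 for exocrine pancreas genes.

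Interferon response genes were lower in 28 of 30 (median -0.20, adjusted p = 4.25e-05), and none passed when adjusted over the list alone. With an estimated correlation the adjusted p of this list was 0.863. Zbp1, a nucleic acid sensor, went from 163.7 ± 15.4 (SD, n = 2) to 104.9 ± 19.1 (SD, n = 6), Igtp, an interferon-inducible GTPase, from 490.5 ± 14.9 (SD, n = 2) to 315.5 ± 56.5 (SD, n = 6), and Irf7, a regulator of type I interferon genes, had a log2 difference of -0.42 ± 0.15 (SE). The GTPase genes Gbp6 (-0.80 ± 0.18, SE) and Irgm2 (-0.62 ± 0.15, SE), outside the list, were among the 12 genes with the smallest p on the lower side. The interferon score was 0.23 and 0.11 in the controls, 0.08 in female OVA 2, 0.12 in male OVA 5 and between -0.16 and -0.11 in the other 4 OVA mice.

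Single genes with the smallest p in which all 6 OVA arrays lay above both controls included Rad1, a DNA damage checkpoint protein, at 26.3 ± 4.45 (SD, n = 2) in controls and 45.2 ± 6.88 (SD, n = 6) in OVA mice (log2 difference 0.73 ± 0.12 SE, adjusted p = 0.241). Tefm, a mitochondrial transcription elongation factor, was 0.67 ± 0.12 (SE) higher, and Rfc3, a subunit of the clamp loader of DNA replication, 0.76 ± 0.15 (SE). Hpgds, the haematopoietic prostaglandin D synthase, went from 26.4 ± 0.153 (SD, n = 2) to 42.1 ± 4.04 (SD, n = 6), and passed when adjusted over the type 2 list alone. Gch1, which starts the synthesis of tetrahydrobiopterin, was 0.43 ± 0.09 (SE) higher and Bcat2, a branched-chain amino acid transaminase, 0.54 ± 0.11 (SE). The other 5 besides Cd8b1 were Prorsd1 (0.82), Hmga2-ps1 (0.70), C030034I22Rik (0.70), Dnajc24 (0.52) and Mir425 (0.52). On the lower side stood Phactr2 (-0.57), the co-receptor Rgmb (-0.65), Psg28 (-0.51), Zfc3h1 (-0.52), the ubiquitin ligase Trim2 (-0.64), Slfn4 (-0.52), the ephrin receptor Epha2 (-0.72), Ppp1r9a (-0.66), Ttc14 (-0.41) and Insyn2a (-0.47), and for Ttc14 and Insyn2a another probe set had the opposite sign. The adjusted p of these 24 genes, Gbp6 and Irgm2 included, was 0.241 to 0.352, so none passed. All OVA arrays lay above both controls for 958 of 11988 genes (8%) and below both for 558 (4.7%), where chance gives 3.6% in each direction.

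Cytokines that define allergic and regulatory responses were mostly too dim to compare. Il4, Il5, Il13, Ifng, Il10, Foxp3, the IgE receptor chain Fcer1a and Tlr4 stayed below the filter, with highest intensities on any array of 10, 7.91, 13.4, 9.68, 5.15, 9.97, 8.86 and 7.99. No probe set named Ighe, the IgE heavy chain, alone. Bcl6, the master regulator of germinal centre B cells and follicular helper T cells, stood at 165.8 ± 20.5 (SD, n = 2) in controls and 247.3 ± 80.9 (SD, n = 6) in OVA mice. Log2 differences were 0.15 ± 0.24 (SE) for Il21, 0.29 ± 0.18 (SE) for Tgfb1, 0.28 ± 0.14 (SE) for Gata3, 0.23 ± 0.17 (SE) for Tbx21, 0.40 ± 0.49 (SE) for the mast cell protease Mcpt1 and 0.24 ± 0.15 (SE) for Cpa3. Igha, the IgA heavy chain, was at 10140 ± 126 (SD, n = 2) and 9364 ± 1380 (SD, n = 6), and Jchain, which joins IgA dimers, at -0.05 ± 0.12 (SE). None of these passed the test.

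The remaining 20 lists did not pass. Type 17 lymphocyte and ILC3 genes came nearest (adjusted p = 0.0597, 8 of 11 higher), and Batf and the lymphoid cytokine Lta (0.87 ± 0.23, SE) passed when adjusted over that list alone. In the other 19 lists only Hpgds of the type 2 list did so. The adjusted p was 0.157 for Paneth cells and for fibroblasts and extracellular matrix, 0.367 for endoplasmic reticulum stress, 0.464 for neurons and glia and 0.489 for immediate early and heat shock genes. It was 0.558 for mast cells and for exocrine pancreas, 0.577 for enteroendocrine and tuft cells, 0.749 for type 1 and cytotoxic lymphocytes, 0.876 for adipocytes and 0.997 for regulatory T cells and oral tolerance. It was 0.718 for each of 8 lists, namely type 2 cytokines and effectors, plasma cells, innate inflammatory genes, the Toll-like receptor pathway, macrophages and dendritic cells, lymphoid stroma and endothelium, the circadian clock and sex chromosome markers. Members with the smallest p in these lists included the plasma cell genes Sdc1 (-0.55 ± 0.17, SE) and Eaf2 (0.70 ± 0.26, SE), the extracellular matrix gene Fn1 (-0.40 ± 0.12, SE), the interleukin chain Il12a (0.72 ± 0.22, SE), the RNA sensor Tlr3 (-0.43 ± 0.16, SE), the Tlr4 partner Ly96 (0.49 ± 0.20, SE), the tuft cell kinase Dclk1 (0.64 ± 0.26, SE), the stress factor Atf3 (-0.62 ± 0.21, SE) and Alox5 of leukotriene synthesis (-0.35 ± 0.13, SE). Exocrine pancreas genes had a median of 0.74, with male OVA 13 at 3.85 above the mean of the 8 arrays, and adipocyte genes stood at 1.18 in male OVA 5. Median, mean and test differed in sign for immediate early genes (median -0.03, mean 0.01, test lower) and stroma (median -0.04, mean 0.06, test lower). The test also pointed lower against a positive median and mean for macrophages (median 0.05) and regulatory T cells (median 0.07), and against a positive median for mast cells, type 1 lymphocytes (median 0.05, mean -0.05) and sex chromosome markers (median 0.01, mean -0.03). Lists of eosinophils and basophils (1 of 16 genes measured), neutrophils (3 of 14) and erythroid cells (2 of 15) held too few genes past the filter to be tested.

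The comparison of the sexes asked which transcripts differed between 3 female and 5 male mice, adjusted for treatment. Glycam1, a mucin-like ligand of L-selectin on the high endothelial venules through which lymphocytes enter lymphoid tissue, was 1234 ± 336 (SD, n = 3) in females and 279.6 ± 78.6 (SD, n = 5) in males, and rose by 2.18 ± 0.23 (SE) on the log2 scale in females (adjusted p = 0.0174). The lowest female lay at 931 and the highest male at 391. Xist, the RNA that silences 1 X chromosome in females, was 1426 ± 157 (SD, n = 3) against 16.1 ± 2.14 (SD, n = 5), a log2 difference of 6.08 ± 0.11 (SE, adjusted p = 4.43e-08). The Y-linked genes Eif2s3y, Kdm5d and Uty fell in females (adjusted p = 9.74e-08, 3.26e-06 and 0.0194). Mean intensities in females and males were 3.02 ± 0.155 and 291 ± 39.8 for Eif2s3y, 2.59 ± 0.567 and 70.01 ± 8.02 for Kdm5d, and 9.88 ± 4.75 and 29.0 ± 2.58 for Uty (SD, n = 3 and 5). For Eif2s3y and Kdm5d the females lay below the constant of 4.88 added before the log, so no fold is given. In all, 12 probe sets passed, 4 of them higher in females (Xist with 3 and Glycam1). The 8 lower ones were those of Eif2s3y, Kdm5d and Uty, and 5 that name several genes or none. Mean intensities of those 5 were 3.88 to 6.35 in females and 25.1 to 279.8 in males. No probe set named the Y-linked gene Ddx3y alone.

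**Figure D3:**
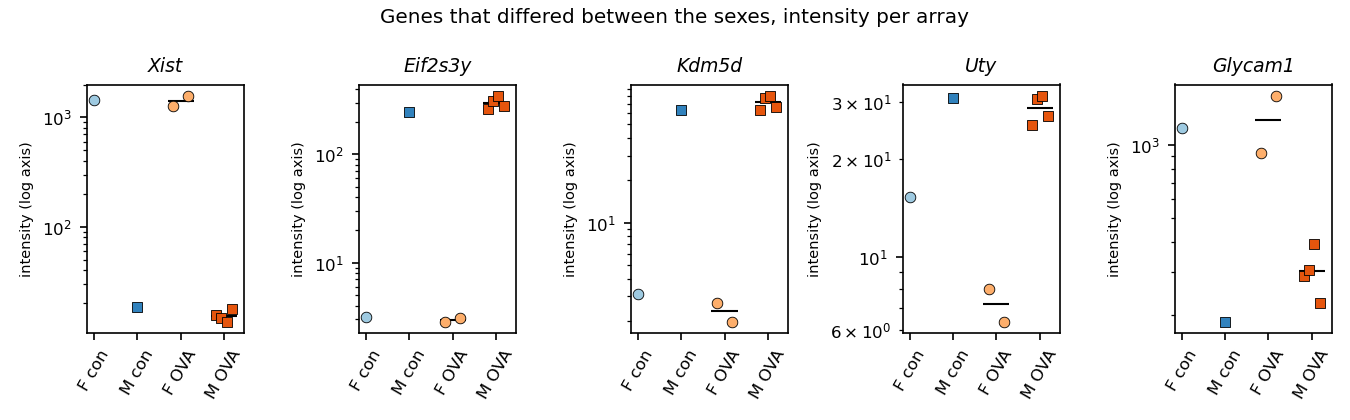
Intensity per array (log axis) of the 5 named genes that passed the test between the sexes, in female and male (F, M) control (con) and OVA mice, each point 1 mouse and each line the mean of a group of more than 1 mouse. For Glycam1 the 3 females lie at 931 or more and the 5 males at 391 or less.

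Below the threshold, the X-linked genes Kdm6a (0.60 ± 0.11, SE) and Eif2s3x (0.62 ± 0.13, SE), both known to escape X inactivation, were higher in females, as were Mdrl (0.65), Pisd-ps3 (0.44), Lrg1 (0.73) and Rad18 (0.54). Hccs, an X-linked gene for a haem lyase of cytochrome c, was 186.1 ± 18.9 (SD, n = 3) in females and 368.8 ± 40.3 (SD, n = 5) in males (adjusted p = 0.0516). Shroom4, also X-linked, was at -1.13 ± 0.16 (SE, adjusted p = 0.121), Acad10 at -0.54, D430042O09Rik at -0.53 and Cyp2j9 at -0.82. An unadjusted p under 0.05 was reached by 1218 probe sets, 324 higher and 894 lower in females, where 1126 were expected by chance. No list score passed the test between the sexes (smallest adjusted p = 0.566). Leaving out either control made the sex difference that of the OVA arrays alone. The adjusted p of Glycam1 was 0.138 when either control was left out, 0.24 without female OVA 12, 0.0761 without male OVA 1 and 0.0647 without male OVA 5, with log2 differences of 2.01 to 2.49 over the arrays left out. The adjusted p of Uty was 0.31 without female OVA 2, 0.221 without female OVA 12, 0.0762 without male OVA 1, 0.0744 without male OVA 5 and 0.0771 without male OVA 13, and that of Shroom4 was 0.0288 when either control was left out.

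The design also asked whether the response to OVA differed between males and females. No probe set passed (limma, smallest adjusted p = 0.485), and 1846 had an unadjusted p under 0.05, 612 with a more positive response in males and 1234 with a more negative one. Among the 5 genes of smallest p on the negative side were Mvd, Hmgcs1, Mvk and Cyp51, enzymes of cholesterol synthesis, with log2 differences of -1.57 ± 0.23, -1.83 ± 0.32, -1.06 ± 0.19 and -1.55 ± 0.28 (SE). Hmgcs1 stood at 442.3 in the female control, 985.3 in the male control, 879.5 on average in 2 female OVA mice and 545 ± 81.1 (SD, n = 4) in male OVA mice. Zfp954 had a difference of -0.92 ± 0.17 (SE). On the positive side, Cyp2c29, a cytochrome P450 of xenobiotic metabolism, had a log2 difference of 2.57 ± 0.45 (SE), from 47.1 in the female control and 23.6 in the male control to 9.08 on average in female OVA and 41.8 ± 12.9 (SD, n = 4) in male OVA mice. Fkbp5, a glucocorticoid-responsive cochaperone, was at 2.05 ± 0.36 (SE), the gastric protease gene Cym at 1.75 ± 0.31 (SE), the sulfotransferase Sult1a1 at 1.60 ± 0.29 (SE) and Trappc13 at 1.16 ± 0.22 (SE), with its second probe set of opposite sign. No list score passed the test of a difference in response between the sexes (smallest adjusted p = 0.958), and enterocytes had the smallest unadjusted p (0.77 ± 0.36, SE). With 1 control per sex, each control stands for its group alone, and the spread came from the OVA mice. Several genes of the proximal small intestine also had their lowest values in both female OVA mice, while Lct, Gip, Gata4 and Cybrd1 did not. Adh6a was at 549.8 and 424.8 in the female and male control. It was 112.7 and 97.7 in female OVA and 365.8 to 1014 in male OVA mice. A difference in gut position cannot be told apart from a response that differs by sex.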

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

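The counts of splits were planned, while the tests of follicle content, RNA degradation, mammary tissue, high endothelial venules, epithelium and gut segment were chosen after the results were seen, the bound for RNA degradation was tightened after its value was seen, and the present test of follicle content replaced an earlier one, a share of 0.107 of splits with a B cell score difference as large, that could not bear on dissection.

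Lists of B cells, germinal centres, T cells and follicular helper T cells were higher in OVA mice and those of barrier genes, goblet cells, enterocytes and crypts lower, among 16 of 36 lists past the threshold with a preset correlation, of which 0 passed with an estimated correlation (smallest adjusted p = 0.863) or fry (0.649). Of the 28 splits into 2 and 6 arrays, 10 gave as many lists, and the highest other split gave 22, so chance is not excluded, and the higher counts of other splits point to a structure of the samples that does not follow treatment. Variation in how much follicle was dissected may contribute, since the B cell and barrier scores were opposed among the 6 OVA mice alone (r = -0.95, exact permutation p = 0.00278), which a response to OVA that varied between mice would also give. RNA degradation cannot be told apart from treatment, because the beta-actin and Gapdh 3′ to 5′ ratios were lower in 5 of 6 OVA mice than in both controls (exact permutation p = 0.179 and 0.107), while the B cell score had rho = -0.05 with the beta-actin ratio (exact permutation p = 0.935) and male OVA 8, with the highest beta-actin ratio, had the highest B cell score. A response of the patch to OVA stays open and was not tested apart from dissection.

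Glycam1 was higher in the 3 females than in the 5 males, at 931 or more against 391 or less. Mammary tissue in female samples is not excluded, because most genes that could test it were dim. The measured mammary genes had a median difference of 0.086 ± 0.193 (SE over 3 genes) where Glycam1 had 2.18. Of these 3, 1 had an unadjusted p under 0.05 (limma), and Lao1 and Krt5 lay at 11.4 to 15.4 and 13.9 to 25.9. The milk genes Csn3, Wap and Lalba did not pass the filter and stayed at 9.96 or below on every array. Csn2 was at 19.2 to 45.2 in females and 14.8 to 32.5 in males. It was highest in female OVA 12, the mouse with the highest Glycam1. The list of high endothelial venules as a whole did not rise in females (median 0.001 ± 0.065, SE over 11 genes and not over mice). Its members differed, 3 of them at an unadjusted p under 0.05 (limma). Madcam1 was 204.2, 250.2 and 406.4 in females and 137 to 270.5 in males, while Chst4 was 59.7, 37.6 and 35.3 in females and 59.7 to 117 in males. More such venules in females are therefore not excluded. The count of 12 probe sets was reached by 2 of 56 splits, the real one included, with 14 in the highest other. Besides that of Glycam1, the 12 are probe sets of Xist, of Y-linked genes, or that name several genes or none. This count therefore says nothing about Glycam1. Regulation of Glycam1 by sex stays open as a hypothesis and may be followed up in more mice, since its adjusted p was 0.24 without female OVA 12.

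Fabp6, the bile acid binding protein of the ileum, was at 21.2 and 21.7 in male OVA 5 and 8 and at 1474 to 3297 in the other 6 mice, and was singled out after its values were seen. Less epithelium is argued against in male OVA 5, whose enterocyte score was 0.33 above the mean of the arrays, and in male OVA 8, where it was -0.18 while Fabp6 lay 4.94 log2 below its mean. Paneth cell scores were the lowest in these mice, at -0.44 and -0.49, and male OVA 8 had -0.58 for goblet and -0.44 for barrier genes. These shortfalls were smaller than that of Fabp6. Patches from a more proximal segment of the gut could give the low Fabp6, because all 8 other measured ileum genes had their lowest values in these 2 arrays, among them Nts, Pyy, Slc51b and Tmigd1 (chance gives 3.6% for each gene). Of 9 proximal genes, 7 had their highest value in male OVA 5, among them Slc40a1, Onecut2 and Adh6a, but 0 in male OVA 8 and 1 had its 2 highest values in these mice, so a segment cannot be told apart from other causes, and the labels give no position along the gut. No biological explanation was tested for this pattern, since both mice belong to a group whose other 2 members had high values. Among proximal genes, Slc40a1, Onecut2, Adh6a, Fabp1 and Cck had their lowest values in both female OVA mice, while Gata4, Cybrd1, Lct and Gip did not. The 9 proximal genes had a median of -0.502 in females against males, 5 at an unadjusted p under 0.05 (limma). A difference in gut position may thus not be confined to male OVA 5 and 8.

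Among the 4 male OVA mice, 200 values were tested for a mouse far from the others. Chance flags about 1 in 20, or 10 of 200, and 16 were found, some because equal values on 2 or 3 arrays narrow the range of the others. In male OVA 8, the intensity was 338 for Edem1 (376 to 381 in the others), 84.5 for Lef1 (53.1 to 53.5), 585 for Gzma (1110 to 1250), 731 for Anxa5 (536 to 559) and 103 for Dclk1 (51.7 to 56.7). The same mouse had 5920 for Cox6a1 (6390 to 6410), 44.1 for Tgfb1 (28.3 to 30.2) and 41 for Mvk (46.8 to 47.7), and a Toll-like receptor pathway score of 6.38 (6.16 to 6.19). In male OVA 5, Reg3b was 2540 (4580 to 4930 in the others), Synpo2 86.7 (127 to 137) and the adipocyte score 8.05 (6.75 to 6.84). In male OVA 1, Phactr2 was 18.5 (20.1 in the others), Tie1 17.6 (17) and the plasma cell score 8.39 (8.35). In male OVA 13, Muc13 was 2210 (1490 to 1570). No named gene passed the test of a difference between the sexes in its response (limma, smallest adjusted p over all probe sets 0.485). None of the 64 AFFX probe sets passed between OVA and control with limma (smallest adjusted p = 0.96, 2 at an unadjusted p under 0.05).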

How the results depend on the processing

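The covariate built from the B cell and barrier scores and the 2 settings that leave out a pair of arrays were chosen after the data were seen. The count for OVA against control was 0 under all 22 alternatives (limma, smallest adjusted p 0.0764 to 0.611), as was that for the difference between the sexes in the OVA effect under the 15 that could be fitted (0.213 to 0.872). Without either control that difference could not be estimated. For the sexes, 12 probe sets became 4 under the stricter filter, which tests fewer probe sets, and 9 to 13 with single arrays left out. The 16 lists became 2 with the score covariate, which is built from 2 of them and so partly fixes the loss of their calls, 0 with an estimated correlation, 0 with fry, and 9 to 18 with single arrays left out (9 without male control 8). With the score covariate, smooth muscle alone of the 16 kept its call, and the other list called was not among them. Array weights ended the calls of the ribosomal (adjusted p = 0.191) and oxidative phosphorylation (0.0562) lists and added fibroblasts (0.0319), and quantile normalization (0.0477) and median centring (0.0377) added the type 17 list. Leaving out male OVA 5 and 8, chosen for low ileal genes, gave 0 probe sets for OVA, 10 for sex and 16 lists, without the ribosomal list (0.109) and with exocrine pancreas (0.0182), a list carried by male OVA 13 that turned lower without that mouse (0.788). Leaving out male control 8 and male OVA 8, chosen for lung genes, gave 0, 13 and 13, without the T cell (0.212), goblet (0.305), crypt (0.0608), smooth muscle (0.167) and ribosomal (0.305) lists and with enteroendocrine cells (0.047) and endoplasmic reticulum stress (0.0477) lower. For Glycam1 the adjusted p was 0.119 without a filter and 0.138 in OVA arrays only, and for Uty 0.0886 without a filter and 0.0737 without the covariate. Hccs passed with quantile normalization (0.0398), median centring (0.046), array weights (0.0162) and no covariate (0.0219), and Shroom4 with array weights (0.00585) and in OVA arrays only (0.0288). The remaining 258 values for the sexes, 135 for the difference and 2723 for OVA kept direction and side of the threshold.

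The 39 reversed values, in 18 genes, were all of OVA against control and none passed the test. Within females log2 differences were 0.032 for Retnlb, -0.083 for Alox15, 0.083 for Reg3b, 0.033 for Pyy, -0.039 for Cela2a, -0.26 for Ctrb1, -0.63 for Prss2 and -0.027 for Eif2s3y. Within males they were -0.034 for Csf3r, -0.018 for Habp2, 0.15 for Ghrl, 0.002 for Bpgm, -0.075 for Il21 and 0.115 for Jchain. With the score covariate they were 0.13 for Slc6a4, 0.016 for Mmp9, 0.073 for Bpgm, -0.032 for Rps19, -0.23 for Il21 and -0.038 for Tgfb1. Alox15 was at -0.003 with a pseudocount of 1 and at -0.025 with median centring. With single arrays left out, values ran from -1.25 to 0.032 for Retnlb, -0.10 to 0.12 for Alox15, -0.034 to 0.14 for Csf3r, -0.018 to 0.37 for Habp2, -0.57 to 0.083 for Reg3b, -1.11 to 0.15 for Ghrl, -1.79 to 0.033 for Pyy, -0.039 to 2.22 for Cela2a, -0.26 to 2.37 for Ctrb1, -0.63 to 1.99 for Prss2, -0.09 to 0.002 for Bpgm, -0.027 to 0.27 for Eif2s3y, -0.075 to 0.41 for Il21 and -0.25 to 0.115 for Jchain. Leaving out an array tests fewer samples, and leaving out a control repeats the contrast within the other sex. Apart from these and the stricter filter the cause was not tested. No scaling moved the median of all genes by more than 0.048 log2. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Genes whose mean over the 8 arrays lay below the filter, at an intensity of 11.9, were not compared, among them Il4, Il5, Il13 and Foxp3.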

Other observations

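All values in this part were singled out after they were seen. Genes of cholesterol synthesis followed the direction of Hmgcs1, Mvd, Mvk and Cyp51 in the difference between the sexes. The 14 other measured genes of the pathway all had a more negative response to OVA in males than in females (median -0.84 log2), 10 of them at an unadjusted p under 0.05, and none passed after adjustment. They included the squalene enzymes Fdft1 (-2.17) and Sqle (-1.99) and the regulator Srebf2 (-1.17). Their mean score, relative to the mean of the 8 arrays, was -0.28 in the female control, 0.28 in the male control, 0.21 and 0.38 in female OVA mice and between -0.25 and 0.01 in male OVA mice. The 14 genes were read on the same arrays as the genes that drew attention to the pathway, so their direction is no independent support. The contrast also rests on 1 control per sex, and these controls lay on opposite sides of the mean.

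In OVA against control, Cyp2c55, Cyp1a1 and Calcb were singled out and did not pass the test. Cyp2c55, a cytochrome P450 of the gut, was at 427.7 ± 129 (SD, n = 2) in controls and 169.2 ± 116 (SD, n = 6) in OVA mice, and Cyp1a1, a target of the aryl hydrocarbon receptor, at 19.2 ± 4.25 (SD, n = 2) and 65.1 ± 29.9 (SD, n = 6). Calcb, a calcitonin gene-related peptide of enteric neurons, was at 33.7 ± 7.14 (SD, n = 2) and 72.9 ± 21.6 (SD, n = 6). Their log2 differences were -1.77 ± 0.46, 1.32 ± 0.35 and 1.04 ± 0.24 (SE).

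Single mice had high values of some genes of other tissues. The lung genes Scgb1a1 and Sftpc were at 323.2 and 185.2 in male control 8 and at 142.8 and 75.1 in male OVA 8, and at 13.3 or less in the other 6 mice. The other lung genes past the filter did not follow, with Scgb3a1 highest in female OVA 2 (21.1) and Ager in female OVA 12 (95.1). Below the filter, Sftpb, Sftpa1, Sftpd, Cyp2f2 and Scgb3a2 had their 2 highest values in male control 8 and male OVA 8. Those values were dim, at 14.8 and 13.6 for Sftpb and 12.2 and 6.25 for Sftpa1. For Bpifa1 and Foxj1 only 1 of the 2 highest values lay in these mice. Male control 8 also had 337.3 for the acute phase gene Saa1, against 51.2 or less in the others. The circadian clock score stood 0.40 above the mean of the arrays in male OVA 5. Female control 7 had the lowest mean Spearman correlation with the other arrays, 0.974 against 0.983 to 0.987. The first 2 principal components held 35.7% and 26.1% of the variance. At an unadjusted p under 0.05, the 2046 tested probe sets that name no gene had 80 higher and 221 lower in OVA mice (median -0.048), and the 19902 that name 1 gene had 1403 higher and 743 lower (median 0.026).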
